A study of Mus musculus with 6 samples.

How the data were processed

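RNA-seq was measured in 6 libraries of mouse colon tissue, 3 labelled Smad4 knockout and 3 labelled Smad4 wild type (called control here), taken 1 month after tamoxifen. Per the labels' protocols, crypts were first released with a chelator, the layer beneath the epithelium was scraped off the muscle, and its RNA was sequenced as 51-base single-end reads, 32000000 to 37000000 per library, of which 86% to 95% mapped uniquely. The labels name the animals as separate mice, so the libraries of a group were treated as biological replicates.

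The deposited table holds, per the file headers, 1 column per library and the columns of a fitted comparison for 22354 genes, given by Ensembl gene ID and symbol. The library columns are whole-number read counts per gene as the authors deposited them, with no normalization. Per the labels' protocols, reads were mapped to the mouse build mm10 with TopHat 2.1.0, counted over annotated genes with HTSeq 0.5.4p5 together with samtools 1.3.1, and tested with edgeR 3.4.2. The submitters' processing notes name Bowtie 0.12.2 and the builds mm8 and mm10, and the column names of the comparison are those DESeq2 writes, so the sources used here do not give a single account of the aligner, the build or the test. Strand handling in the counting is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The mean normalised signal per gene, the log2 fold change, its standard error and test statistic (2 score columns), the p-value and the adjusted p-value are the authors' deposited values. They were used only where the text names the authors' deposited table. For Ccr6 that log2 fold change lies closer to 0 than a fit to the deposited counts gave (1.46, against 2.08 with edgeR), and no shrinkage is stated in the sources used here. An adjusted p-value was given there for 14530 genes and left empty for 7824, and 70 genes carry a short note by the authors. No listed gene is at 0 in all 6 libraries.

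Library totals were 18918880 to 25867997 counts. A count of 3 corresponds to 0.116 to 0.159 counts-per-million units (CPM), and this is counting error only. No row lacks a gene name, so all rows entered the totals. Of the gene IDs, 21925 (98.1%) were found in GENCODE M21 (mm10), which gave the coordinates, and 2763 of these carry another symbol there. Symbols are printed as the deposited table gives them (Faim3 for Fcmr, Igj for Jchain). The counts of every pair of libraries within a group differed by more than sampling noise, so none was treated as a repeat of another.

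Counts were scaled by TMM, genes were filtered with filterByExpr, and knockout was compared with control by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with group as the sole term. The Benjamini-Hochberg adjustment covered all 14180 tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries. Adjusted p-values with no tool named are from this test. The test fits the deposited unit, since the values are raw counts. Permuting 3 against 3 libraries cannot give a two-sided p below 0.1.

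Before the data were examined, 34 gene lists were fixed for pathways and for the cell types that scraped colon tissue could hold. The 26 lists with at least 5 tested members were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were the alternatives. The other 8 lists are given as values. Members were also adjusted over the list alone. "Rose" and "fell" are used of list members that passed that adjustment, of lists that passed camera, and of genes past the threshold of a tool named beside them.

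The rule for named genes, also fixed before the data were examined, took Smad4, Lrig1, Ccr6 and Ccl20 whatever their test. It took the 10 largest rises and 10 largest falls among genes past the threshold with a mean CPM of at least 1 and no overlap between groups, leaving out predicted genes (Gm or Rik names), pseudogenes and immunoglobulin or T cell receptor variable segments, which are described as a class. With fewer than 5 such genes, it took the 10 with the smallest unadjusted p under the same conditions, named as not past the threshold. It also took up to 4 members of each list with the smallest p. Other genes are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

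Alternatives were other scalings (RLE, upper quartile, totals), no count filter, a mean count of at least 10, DESeq2 1.42.0, the edgeR exact test, limma-voom, the replicate number as a block, a threshold of 0.1, the omission of immunoglobulin, T cell receptor and mitochondrial genes, and the omission of each library in turn. The omission of each library with DESeq2 and with the exact test was added after the data were seen. Adjusted p-values that DESeq2 left empty stayed empty.

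The scripts were tested on simulated counts for the knockout against control comparison, with 3 libraries a side and 14041 genes (14180 for DESeq2). Of 100 genes changed 2-fold, the quasi-likelihood test recovered 80%, DESeq2 87%, the exact test 87% and limma-voom 81%. Of 100 changed 4-fold, these recovered 97%, 98%, 100% and 96%. False calls numbered 9, 47, 53 and 10, and with no simulated change 0, 5, 5 and 0. A simulated 2-fold rise of the B cell list over 26 lists was called by camera with the preset correlation (adjusted p = 2.23e-34) and with an estimated one (adjusted p = 0.00425), with 1 other list called. Simulated genes were drawn independently of each other, with no library set apart. In the real libraries the estimated correlation of the B cell list was 0.837. The simulation therefore checks the scripts and does not give the power of these tests on the real libraries.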

Results

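Colon tissue from 6 mice was profiled by RNA-seq 1 month after tamoxifen, which switches on the gene deletion in inducible knockout lines. The 3 libraries labelled Smad4 knockout were compared with 3 labelled wild type. Smad4 is the shared signal transducer of the TGF-beta and BMP pathways, and Lrig1, which the genotype names, marks stem and progenitor cells of the intestinal epithelium. The tissue was the layer that remained after removal of crypts and was scraped off the muscle, and its label is stroma. The label is kept here, although the levels of epithelial and collagen genes given next argue against RNA mainly from a layer freed of its crypts. Control libraries held 20852408, 18918880 and 25867997 counts and knockout libraries 21194104, 21344315 and 22821486, over 18671 to 19193 detected genes.

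Transcripts of epithelial cells were the most abundant of the cell type markers in all 6 libraries. The 25 epithelial markers summed to 46330 ± 5340 CPM in control and 44190 ± 2109 CPM in knockout (SD, n = 3 each). The fibroblast, smooth muscle and blood endothelial lists together summed to 804.8 to 953.8 CPM per library. The ratio of the epithelial sum to this stromal sum was between 42.6 and 60.3 across the libraries. Smooth muscle genes summed to 550.4 CPM in control, where Des, Acta2 and Myh11 had means of 4.0, 3.05 and 2.1 CPM. Acta2 and Myh11 were chosen after their values were seen. The stromal sum may therefore hold transcripts of other cells, and the ratio may understate the lead of epithelial transcripts. Among genes chosen after their values were seen, Epcam, an adhesion molecule of epithelial cells, stood at 2198 ± 47.9 CPM in control and 2382 ± 109.2 CPM in knockout. The polymeric immunoglobulin receptor Pigr stood at 9002 ± 447.9 and 8864 ± 253.3 CPM. The fibrillar collagen gene Col1a1, chosen in the same way, stood at 0.504 ± 0.196 and 1.12 ± 0.665 CPM. None of the 25 tested epithelial markers passed when adjusted over the list alone or over all genes, and camera gave an adjusted p of 0.968 for the list. Chga, a granule protein of enteroendocrine cells, had the smallest p of the list, with a log2 fold change of -0.34 ± 0.08 (SE). Muc2, the main secreted mucin of goblet cells, had -0.26 ± 0.16, and Car1, a carbonic anhydrase of colonocytes, -0.80 ± 0.49.

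**Figure D1:**
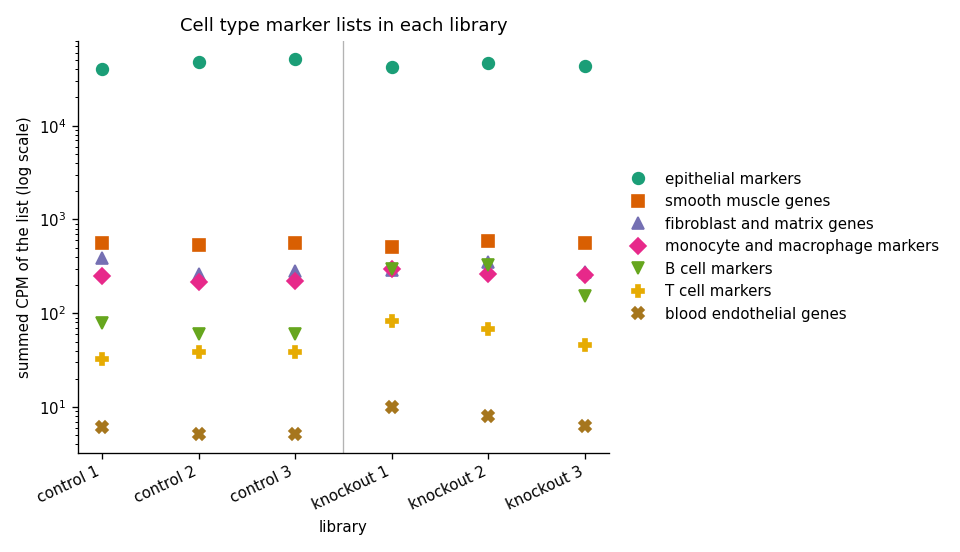
Summed TMM-scaled CPM of 7 marker lists (log axis) in each of the 3 control and 3 knockout libraries, 1 point per list and library. Epithelial markers lie between 40510 and 51010 CPM in all libraries, and B cell markers lie at 60.2 to 79.3 CPM in control and 151.8 to 326.6 CPM in knockout.

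The level of the targeted gene was compared first. Smad4 (ENSMUSG00000024515, chromosome 18, 73639009 to 73703780, mm10, minus strand, protein coding) was at 131.6, 152.5 and 110.9 CPM in the control libraries and at 91.9, 102.1 and 59.0 CPM in the knockout libraries. The knockout mean was 64.0% of the control mean, from 131.7 ± 20.8 to 84.3 ± 22.5 CPM (SD, n = 3 each). All 3 knockout libraries lay below all 3 controls. The log2 fold change of -0.64 ± 0.21 (SE) did not pass the threshold (adjusted p = 0.338), nor did it with DESeq2 (adjusted p = 0.0736). The counts cover the whole gene, and the deleted part is not given in the labels, so reads from outside it would still be counted. Lrig1 (ENSMUSG00000030029, chromosome 6, 94604529 to 94700158) was at 91.1 ± 31.6 CPM in control and 92.4 ± 14.3 CPM in knockout, a difference smaller than the spread between replicates (log2 fold change 0.02 ± 0.23, adjusted p = 0.995).

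The list of TGF-beta and BMP pathway targets, taken as a whole, showed no common direction. Of its 16 tested members, 8 had a positive and 8 a negative fold change, none passed when adjusted over the list alone or over all genes, and the list did not pass camera (adjusted p = 0.722). Tgfb1, the ligand itself, was at 7.55 ± 0.562 CPM in control and 11.7 ± 2.58 CPM in knockout. The BMP target Id3 was at 167.4 ± 47.4 and 79.7 ± 46.2 CPM. Atoh8 had a log2 fold change of -0.97 ± 0.30 and Pmepa1 one of 0.52 ± 0.20. Id1, Id2 and Smad6, chosen after their values were seen, had -0.775 ± 0.319, -0.627 ± 0.315 and -0.708 ± 0.295. These were lower together with Id3 and Atoh8, so the even split does not show that BMP targets were unchanged. Targets of the BMP pathway were not tested apart.

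The series title names Ccr6, the receptor of the chemokine Ccl20, which is carried by B cells and by type 3 lymphocytes. Ccr6 (ENSMUSG00000040899, chromosome 17, 8236043 to 8257141, plus strand) was 4.22-fold higher in the knockout mean, at 1.3 ± 0.34 CPM in control and 5.48 ± 2.48 CPM in knockout (SD, n = 3 each). It was counted 31, 29 and 23 times in the control libraries and 154, 142 and 59 times in the knockout libraries. The log2 fold change was 2.08 ± 0.41 (SE), with all 3 knockout libraries above all 3 controls. It rose when adjusted over the list alone, among 15 chemokine receptors (adjusted p = 0.00551), and with DESeq2 (adjusted p = 1.28e-04), but not over all genes in the quasi-likelihood test (adjusted p = 0.113). That test passed it without knockout replicate 3 (log2 fold change 2.43, adjusted p = 0.00736) and with no low-count filter (adjusted p = 0.0291). In the authors' deposited table its log2 fold change was 1.46 with an adjusted p of 2.14e-04. How the study came to Ccr6 is not given in the sources used here, so its rise is not counted as independent evidence. Its ligand Ccl20 (ENSMUSG00000026166, chromosome 1, 83116766 to 83119167) was at 5.37 ± 2.61 CPM in control and 8.5 ± 0.97 CPM in knockout and did not pass (log2 fold change 0.66 ± 0.31, adjusted p = 0.635).

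**Figure D2:**
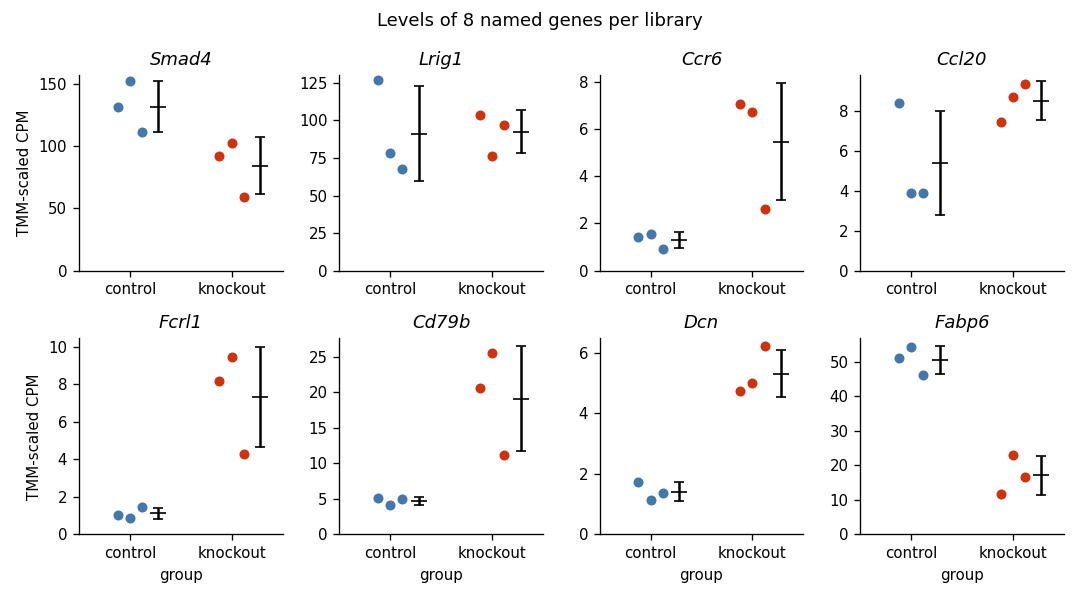
TMM-scaled CPM of 8 genes in 3 control (blue) and 3 knockout (red) libraries, 1 point per library, with the group mean and SD beside the points (black). Ccr6 has means of 1.3 and 5.48 CPM and Smad4 means of 131.7 and 84.3 CPM, without overlap between the groups in either gene.

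Across all genes, the knockout libraries held higher levels of B lymphocyte genes and of decorin, and a lower level of a bile acid carrier. No gene passed the quasi-likelihood test of edgeR at an adjusted p of 0.05, where the smallest value was 0.0958. By unadjusted p under 0.05, 1211 of 14180 genes differed (736 higher and 475 lower in knockout), with 709 expected by chance. DESeq2 called 336 genes (291 higher, 45 lower), the edgeR exact test 381 (335 higher, 46 lower) and limma-voom 0. Of these, 315 genes were called by DESeq2, by the exact test and in the authors' deposited table, which holds 415 calls. The groups did not overlap for 13.3% of tested genes, where chance gives 10%. The quasi-likelihood count was 266 without knockout replicate 3 and 17 without control replicate 1, and 157 with no low-count filter. DESeq2 called 142 without knockout replicate 1 and 221 without control replicate 3, and the exact test 190 and 248 without these and 608 without control replicate 1.

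The 10 genes with the smallest p were therefore named as not past the threshold of the quasi-likelihood test, each with an adjusted p of 0.0958, and DESeq2 called all of them. Fcrl1, an Fc receptor-like protein of B cells, had a log2 fold change of 2.69 ± 0.35 (SE), from 1.12 ± 0.293 to 7.31 ± 2.68 CPM (chromosome 3, 87376387 to 87402934). Cd79b, a chain of the B cell receptor complex, stood at 4.70 ± 0.544 CPM in control and 19.1 ± 7.34 CPM in knockout (chromosome 11, 106311341 to 106314762). Btla, an inhibitory receptor of lymphocytes, had a log2 fold change of 2.09 ± 0.26, Faim3, the receptor for the Fc part of IgM, 2.23 ± 0.30, and Tnfrsf13c, the receptor for BAFF, 2.03 ± 0.29. Pyhin1, an interferon-inducible gene, had 2.07 ± 0.30 and the surface protein gene Ly6d 1.90 ± 0.25. Dcn, the small matrix proteoglycan decorin made by fibroblasts, stood at 1.41 ± 0.310 CPM in control and 5.31 ± 0.791 CPM in knockout (chromosome 10, 97479609 to 97518143). Pgap1, an enzyme of GPI anchor maturation, had a log2 fold change of 0.86 ± 0.12. Fabp6, the cytosolic bile acid binding protein, was the single gene of the 10 that was lower, at 50.5 ± 4.12 CPM in control and 17.1 ± 5.62 CPM in knockout (log2 fold change -1.56 ± 0.22, chromosome 11, 43596049 to 43601540).

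B cell markers rose together. All 21 tested members of the list were higher in knockout and passed when adjusted over the list alone, none passed over all genes, and DESeq2 called 20. The median log2 fold change was 2.03, and the summed level was 66.7 ± 11.0 CPM in control and 259.1 ± 93.9 CPM in knockout (SD, n = 3 each). Camera called the list as higher (adjusted p = 5.31e-32), and this call did not hold with an estimated correlation (adjusted p = 0.285). The list for lymphoid follicles and germinal centres had 10 of 14 members that rose when adjusted over the list alone (camera adjusted p = 2.34e-12, adjusted p = 0.286 with an estimated correlation). Of these, Gpr183, which guides B cells within follicles, had a log2 fold change of 1.95 ± 0.32. The B cell and follicle lists share Cxcr5 and Tnfrsf13c. The 3 libraries with these higher levels held the epithelial marker sum given above, at 44190 CPM against 46330 CPM in control. That sum lies so far above the B cell level that near-equal values cannot show equal tissue make-up.

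Part of the plasma cell genes, and immunoglobulin segments, were also higher. Of 15 tested plasma cell genes, 8 rose when adjusted over the list alone and none over all genes, with a median log2 fold change of 1.81 (camera adjusted p = 3.89e-08, adjusted p = 0.285 with an estimated correlation). Ighm, the constant region of IgM, was at 16.3 ± 3.13 CPM in control and 57.5 ± 23.6 CPM in knockout. The transcription factor gene Irf4 had a log2 fold change of 2.13 ± 0.35, and Pou2af1, a coactivator in B cells, 1.94 ± 0.33. Prdm1, Xbp1 and Sdc1 of this list had 0.12 ± 0.18, 0.07 ± 0.10 and 0.19 ± 0.12. Igkc was at 653.1, 304.0 and 136.7 CPM in knockout and at most 136.2 CPM in control. These 4 genes were chosen after their values were seen. The list therefore does not show a rise of plasma cells apart from that of B cells. The light chain gene Iglc2 had 2.39 ± 0.48 (1.73 ± 0.32 without knockout replicate 1), and reads of light chain constant regions can be shared between near-identical copies. All 31 tested immunoglobulin variable segments had a positive fold change, 23 of them at an unadjusted p under 0.05, and their summed level was 27.0 ± 10.5 CPM in control and 89.6 ± 50.9 CPM in knockout.

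T cell markers rose less. All 20 tested members had a positive fold change, 11 rose when adjusted over the list alone, none over all genes and 5 with DESeq2. The median log2 fold change was 0.98 (camera adjusted p = 1.53e-14, adjusted p = 0.286 with an estimated correlation). Cd4, the co-receptor of helper T cells, was at 1.3 ± 0.235 CPM in control and 3.70 ± 1.49 CPM in knockout, and the co-stimulatory receptors Icos and Cd28 had log2 fold changes of 1.67 ± 0.44 and 1.6 ± 0.31. Within each library, the mean log2 level of the B cell list minus that of the T cell list was 1.00 ± 0.25 (SE) higher in knockout. The 12 cytotoxic and type 1 lymphocyte genes passed camera (adjusted p = 2.37e-04, adjusted p = 0.341 with an estimated correlation), although no member passed when adjusted over the list alone. Prf1, which encodes perforin, had a log2 fold change of 1.24 ± 0.35. The 6 regulatory T cell genes passed camera (adjusted p = 0.0369, adjusted p = 0.288 with an estimated correlation) with no member past the list alone, and the call was lost without control replicate 2 (adjusted p = 0.192), without knockout replicate 1 (adjusted p = 0.368) and with a mean count of at least 10 (adjusted p = 0.0854).

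Of 15 chemokine receptors, 5 rose when adjusted over the list alone (Cxcr4, Cxcr5, Ccr6, Ccr7 and Cxcr6), none over all genes, and camera called the list (adjusted p = 6.01e-05, adjusted p = 0.288 with an estimated correlation). Cxcr4, the receptor of Cxcl12, was at 2.93 ± 0.599 CPM in control and 13.1 ± 5.39 CPM in knockout. Cxcr6 was chosen after its values were seen. Of 19 chemokine ligands, Cxcl13, which draws B cells into follicles, was the single member that rose when adjusted over the list alone (log2 fold change 2.62 ± 0.55), and the list did not pass camera (adjusted p = 0.0569), although it did without control replicate 1 (adjusted p = 0.00158), without knockout replicate 2 (adjusted p = 0.0363) and with no low-count filter (adjusted p = 0.0247). Of 12 type 3 genes, 3 rose when adjusted over the list alone, namely Ccr6 and the lymphotoxin genes Ltb (log2 fold change 1.62 ± 0.34) and Lta (1.49 ± 0.36). The type 3 list passed camera (adjusted p = 0.00862, adjusted p = 0.443 with an estimated correlation), and the call was lost without knockout replicate 2 (adjusted p = 0.133). The receptor and type 3 counts hold Ccr6, which the title names, and are not counted as wholly independent evidence.

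Lists of myeloid cells rose by camera. Of 16 monocyte and macrophage markers, Lyz2, a lysozyme, rose when adjusted over the list alone, from 10.5 ± 2.07 to 33.8 ± 16.0 CPM, and 15 had a positive fold change, with a median of 0.40 on the log2 scale. Camera called the list (adjusted p = 5.61e-04, adjusted p = 0.288 with an estimated correlation). Of 8 dendritic cell markers, Ccr7, Fscn1 and Flt3 rose when adjusted over the list alone, and the list passed camera (adjusted p = 0.00231, adjusted p = 0.286 with an estimated correlation) except without knockout replicate 1 (adjusted p = 0.0511). Of 13 inflammatory cytokines and effectors, 4 rose when adjusted over the list alone and 1 fell. The endothelial adhesion molecule Vcam1 had a log2 fold change of 1.90 ± 0.42, Il1b 1.52 ± 0.42, Il18 0.67 ± 0.15 and Socs3 0.47 ± 0.12, and Nfkbia, an inhibitor of NF-kappaB chosen after its values were seen, had -0.32 ± 0.10. The inflammatory list passed camera (adjusted p = 0.0141, adjusted p = 0.286 with an estimated correlation), and the call was lost without control replicate 2 (adjusted p = 0.0619), knockout replicate 2 (adjusted p = 0.0676) or knockout replicate 3 (adjusted p = 0.107). The 5 mast cell and eosinophil genes did not pass (adjusted p = 0.769). Of the 4 neutrophil genes, Il1b and S100a8 rose when adjusted over the list alone but not over all genes (adjusted p = 0.239 and 0.328).

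MHC class II genes split in direction. Of 19 tested genes of the interferon-gamma and MHC class II list, 3 rose and 9 fell when adjusted over the list alone, and none passed over all genes. Those that rose encode the peptide exchange regulators H2-Oa and H2-Ob and the chain H2-DMb2, with H2-Ob at 4.52 ± 1.63 CPM in control and 17.8 ± 4.83 CPM in knockout. Those that fell include H2-DMb1, at 126.9 ± 6.70 CPM in control and 96.1 ± 2.23 CPM in knockout, and H2-Aa, chosen after its values were seen, at 991.0 ± 98.0 and 718.5 ± 33.9 CPM. H2-DMb1 and H2-DMb2 are close copies, so reads can be shared between them. The median log2 fold change of the list was -0.29, its mean was 0.02, and camera called it as lower (adjusted p = 0.00231, adjusted p = 0.443 with an estimated correlation), but not without control replicate 1 (adjusted p = 0.0774). Of 22 interferon-stimulated genes, 21 had a negative fold change, with a median of -0.32, and the list fell by camera (adjusted p = 9.50e-08, adjusted p = 0.288 with an estimated correlation). No interferon-stimulated gene passed when adjusted over the list alone, and DESeq2 called Irf7, which stood at 148.4 ± 23.4 CPM in control and 105.7 ± 6.59 CPM in knockout. Isg15 had a log2 fold change of -0.55 ± 0.17.

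Mitochondrially encoded genes fell. All 7 tested members fell when adjusted over the list alone, none passed over all genes and DESeq2 called all 7, with a median log2 fold change of -0.51. Camera called the list (adjusted p = 3.55e-11, adjusted p = 0.285 with an estimated correlation). All genes with mitochondrial names, rRNA and tRNA genes included, took 2.64%, 2.64% and 3.0% of the counts in control and 2.06%, 2.01% and 1.77% in knockout. The complex I gene mt-Nd6 was at 1074 ± 78.3 CPM in control and 712.2 ± 14.4 CPM in knockout, and mt-Nd2 and mt-Nd5 had log2 fold changes of -0.51 ± 0.09 and -0.57 ± 0.10. All 21 cell cycle genes had a negative fold change, with a median of -0.22 on the log2 scale and none past the list alone. The cell cycle list fell by camera (adjusted p = 6.60e-05, adjusted p = 0.462 with an estimated correlation), and the call was lost without control replicate 1 (adjusted p = 0.127). Birc5, an inhibitor of apoptosis needed for cell division, was at 52.6 ± 5.76 CPM in control and 41.5 ± 5.21 CPM in knockout.

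**Figure D3:**
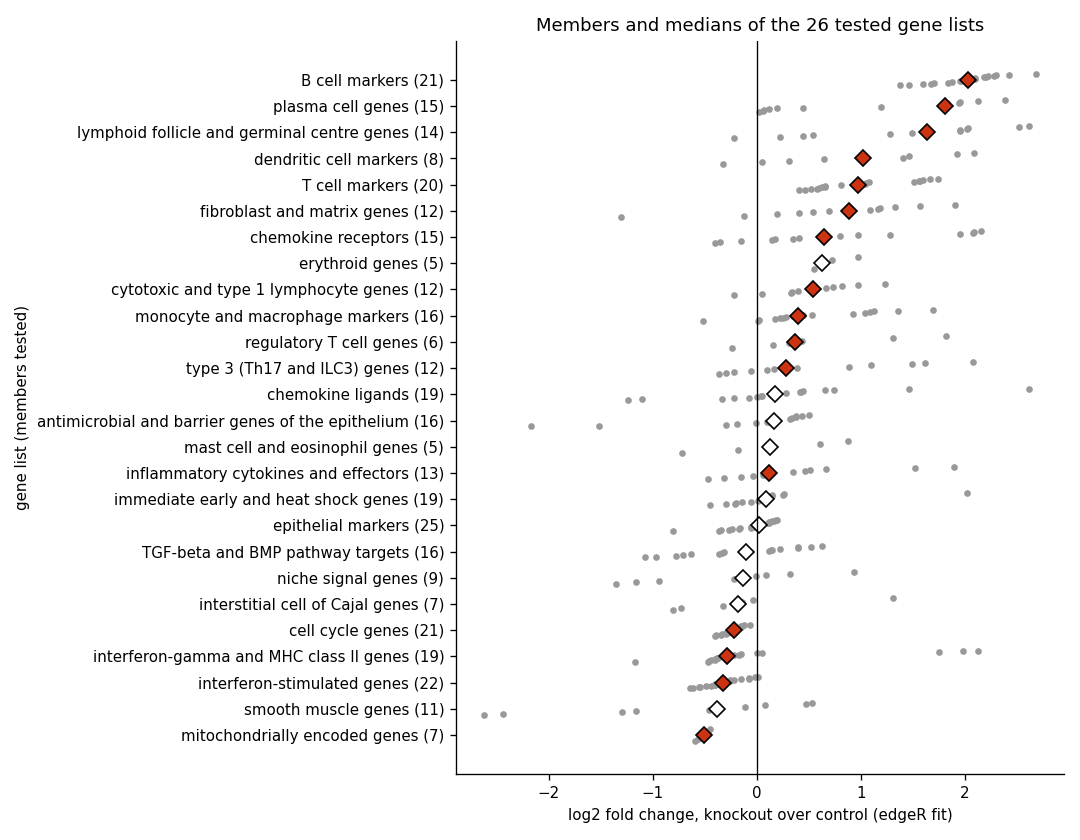
Log2 fold change of knockout over control for each tested member (grey points) and the median (diamond) of the 26 tested gene lists, ordered by median, with the number of tested members in brackets. Red diamonds mark the 16 lists past an adjusted p of 0.05 by camera with the preset correlation, from B cell markers at 2.03 to mitochondrially encoded genes at -0.51, and white diamonds the others.

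Among mesenchymal lists, fibroblast and matrix genes were called as higher by camera, with a median log2 fold change of 0.89 (adjusted p = 6.60e-05, adjusted p = 0.285 with an estimated correlation). Their summed level did not rise, at 311.1 ± 66.4 CPM in control and 305.9 ± 42.3 CPM in knockout. The members named below make up little of this sum, so it does not follow them. The mean log2 CPM of tested members was 1.01 ± 0.204 in control and 1.66 ± 0.213 in knockout. Of 12 tested members, Dcn, Col1a2 and Pdgfra rose and Fbn1 fell when adjusted over the list alone, none passed over all genes, and DESeq2 called 1. Col1a2, a collagen I chain, was at 0.603 ± 0.171 CPM in control and 1.79 ± 0.901 CPM in knockout, and Pdgfra at 0.224 ± 0.101 and 0.551 ± 0.0818 CPM. Fbn1, a microfibril protein, was at 1.38 ± 0.529 and 0.556 ± 0.230 CPM. The 11 smooth muscle genes did not pass camera (adjusted p = 0.378), except without control replicate 2 (adjusted p = 0.0238). Des, the muscle intermediate filament desmin, was at 10.95, 0.859 and 0.199 CPM in the control libraries and at 0.919, 0.665 and 0.355 CPM in the knockout libraries. The 9 niche signal genes (adjusted p = 0.854) and the 7 genes of interstitial cells of Cajal (adjusted p = 0.825) did not pass. Prkcq of the latter list rose when adjusted over the list alone (log2 fold change 1.31 ± 0.31). The other 6 members had negative fold changes, so Prkcq does not stand for that cell type.

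The remaining lists gave no call by camera over all 6 libraries. Antimicrobial and barrier genes of the epithelium did not pass camera (16 genes, adjusted p = 0.137), except without control replicate 3 (adjusted p = 0.0162). Within this list S100g, a calcium-binding protein of absorptive cells, had a log2 fold change of -2.17 ± 0.56 (-1.21 ± 0.26 without control replicate 3) and did not pass over the list alone. Immediate early and heat shock genes did not pass (19 genes, adjusted p = 0.323), with Egr2 rising when adjusted over the list alone (2.02 ± 0.42 on the log2 scale). The 5 erythroid genes did not pass (adjusted p = 0.144), except without knockout replicate 2 (adjusted p = 0.00564). Fewer than 5 members were tested in the other lists. Of these, Pecam1 of 3 blood endothelial genes rose when adjusted over the list alone, from 1.74 ± 0.338 to 3.62 ± 1.35 CPM, as did Ret of 3 enteric neuron genes (0.72 ± 0.23 on the log2 scale). An adjustment over 3 genes is slight, and neither passed over all genes (adjusted p = 0.317 and 0.328). No member did so among 3 lymphatic endothelial, 3 adipocyte, 1 enteric glia, 1 pancreatic acinar and 4 sex-linked genes. The Y-linked genes Kdm5d and Ddx3y were at 54.1 ± 0.524 and 46.1 ± 2.08 CPM in control and at 51.1 ± 2.22 and 46.9 ± 4.50 CPM in knockout.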

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

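The omission of single libraries with DESeq2 and with the exact test was chosen after the data were seen. The count of called genes was 0 with limma-voom, and 0 in the quasi-likelihood test of edgeR with every scaling (RLE, upper quartile, totals), with a mean count of at least 10 and without immunoglobulin, T cell receptor and mitochondrial genes, where 1145 to 1218 genes had an unadjusted p under 0.05. It was 157 with no low-count filter, 336 with DESeq2, 381 with the exact test and 92 at an adjusted p of 0.1. Without each library in turn it ranged from 0 to 266, with 17 calls without control replicate 1, 266 without knockout replicate 3 and 0 in the other 4 fits. DESeq2 gave 142 to 483 calls without a library (142 without knockout replicate 1, 221 without control replicate 3), and the exact test 190 to 608 (190 without knockout replicate 1, 248 without control replicate 3, 608 without control replicate 1). In the simulated counts DESeq2 and the exact test made 47 and 53 false calls, against 9 with the quasi-likelihood test and 10 with limma-voom. Calls that rest on DESeq2 or the exact test alone may therefore hold more false ones than their threshold states. Whether this is the whole cause of the gap between the tests was not tested.

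Smad4 stayed lower and short of the threshold in every alternative listed above over 6 libraries and in each quasi-likelihood fit without a library (log2 fold change -0.803 to -0.429 there, adjusted p 0.0736 to 0.703), and DESeq2 passed it without knockout replicate 2 (adjusted p = 0.0357). Ccr6 stayed higher in each alternative fitted for it (single libraries were not left out with the exact test), at 2.098 with no low-count filter (adjusted p = 0.0291, within 1.28e-04 to 0.401 over the alternatives chosen beforehand), 2.09 with DESeq2 and 2.08 with the exact test, and these 3 passed it over all 6 libraries. Without each library in turn it ranged from 1.855 to 2.432, past the threshold in the quasi-likelihood test without knockout replicate 3 and in all 6 fits of DESeq2 (adjusted p 2.50e-10 to 0.0352). Of the 16 lists called by camera, 0 remained with an estimated correlation and 0 with fry. The estimated correlations of these lists ran from 0.0338 (inflammatory list) to 0.864 (cell cycle list), with 0.837 for B cell markers. All lay above the preset 0.01, which takes members that vary together as nearly independent. The adjusted p-values with the preset are therefore too small for the lists of high correlation. Whether this is the whole cause was not tested. The other list settings over all 6 libraries called 15 to 18.

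The labels do not say whether the replicate numbers pair the libraries. The deviations of same-numbered libraries correlated at -0.052, -0.143 and 0.143, which showed no pairing but cannot exclude one. With the replicate block 0 genes (1254 at an unadjusted p under 0.05) and 16 lists were called. Smad4 (-0.668 ± 0.101, SE, adjusted p = 0.105) and Ccr6 (1.998 ± 0.242, adjusted p = 0.0888) stayed short of the threshold there. Their SEs were 0.206 and 0.414 without the block, so a pairing stays open. No list called by camera changed direction in any alternative, while some lists short of the threshold did, such as epithelial markers and interstitial cell of Cajal genes with fry and without control replicate 1. Alternatives for normalized values (pseudocounts, value filter) did not apply to counts. Ccr6 rests on 23 to 154 counts per library, and levels under 0.159 CPM lie below 3 counts in the shallowest library.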

Other observations

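Gp2, Spib, Trpv6, Axin2, Il18bp and Slc30a10 were chosen after their values were seen, as were the tests of the epithelial share, of Ccr6 against the B cell list, of uneven sampling and of Hox position. Gp2, a receptor of M cells, which overlie lymphoid follicles, stood at 0.414 ± 0.327 CPM in control and 3.86 ± 1.72 CPM in knockout (log2 fold change 3.24 ± 0.61, SE, and 4.02 ± 0.66 without control replicate 1, adjusted p = 1.14e-05 with DESeq2). Spib, a transcription factor of both B cells and M cells, rose from 9.45 ± 0.384 to 26.2 ± 7.91 CPM (adjusted p = 1.89e-07 with DESeq2). Trpv6, an apical calcium channel, fell from 57.5 ± 20.4 to 15.5 ± 8.60 CPM (adjusted p = 0.0278 with DESeq2), and the Wnt target Axin2 from 40.1 ± 2.48 to 22.7 ± 6.21 CPM (adjusted p = 0.00244 with DESeq2). Il18bp, which binds the cytokine IL-18, fell from 47.5 ± 2.0 to 32.4 ± 2.56 CPM (adjusted p = 3.17e-04 with DESeq2), while Il18, one of the list members named above, had a log2 fold change of 0.67 ± 0.15 (adjusted p = 0.00638 with DESeq2). With the quasi-likelihood test over all genes and all 6 libraries these 6 genes stayed short of the threshold, but with no low-count filter it passed Gp2 (adjusted p = 0.0232), Spib (adjusted p = 0.0169), Trpv6 (adjusted p = 0.0334) and Il18bp (adjusted p = 0.0291). Without knockout replicate 3 it passed Spib (adjusted p = 0.00341) and Il18bp (adjusted p = 0.0295), and n was 3 libraries a side.

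Without control replicate 1, the quasi-likelihood test called 17 genes, 12 of them lower in knockout. Car1 had a log2 fold change of -1.23 ± 0.12 (adjusted p = 0.0249), the lipase gene Lpl -1.48 ± 0.15, and the manganese transporter gene Slc30a10 -2.16 ± 0.25 (adjusted p = 0.0335). Among the 5 that were higher were Dcn (2.09 ± 0.24) and H2-Ob (2.32 ± 0.28). Hoxb6, chosen after its values were seen, was also called as lower (-1.24 ± 0.16, adjusted p = 0.0484). In control replicate 1 itself Car1 was at 1169 CPM, against 5248 and 5414 CPM in the other controls and 2068 to 2605 CPM in knockout. Lpl, Slc30a10 and Hoxb6 were likewise lowest of all libraries there, at 2.43, 4.68 and 8.94 CPM. The differences of these genes from control therefore rest on the other 2 control libraries. A difference in colon position between libraries cannot be told apart from one of genotype here.

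Epithelial transcripts led all 6 libraries labelled stroma. The summed CPM of the epithelial list exceeded that of the fibroblast, smooth muscle and blood endothelial lists 42.6 to 60.3 times, with a ratio above 10 in 6 of 6 libraries. A minority of epithelial RNA in a mainly stromal preparation is argued against, since the abundant collagen genes of stroma (Col1a1, Col1a2 and Col3a1) reached at most 3.37 CPM in any library, where Epcam, Krt8 and Pigr stood at no less than 2143 CPM. Marker sums are not shares of RNA and the ratios restate the pattern, so they cannot give the share of RNA from epithelium. The levels of these collagen and epithelial genes argue against RNA mainly from stroma in all 6 libraries. Whether the deposited table comes from tissue that kept its crypts, or from another preparation of the same mice, stays open and was not tested, and it bears on every value labelled stroma.

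B cell genes, and Ccr6 with them, were higher in the knockout libraries. A lower share of epithelium that raises every other cell type alike would move the lists alike. The B cell list rose over the macrophage list by 1.401 ± 0.133 (SE, log2) and over the smooth muscle list by 2.18 ± 0.45. Control replicate 1 widened the difference from the smooth muscle list (B cell minus smooth muscle -2.199 there, -0.883 and -1.245 in the other controls). These list means cannot decide, since macrophage list members differed. Lyz2, Csf1r and C1qa had log2 fold changes of 1.69, 1.36 and 1.13. Cd14 and Mertk, chosen after their values were seen, had 0.02 and 0.01. Whether such flat members come from other cells was not tested. The T cell, macrophage and fibroblast lists were also called as higher by camera, and the smooth muscle list was not. A rise across cell types, of equal or unequal size, therefore stays open. Ccr6 may follow the B cell content of a library, since its difference from the B cell list changed by -0.001 ± 0.239 between the groups. Uneven sampling of lymphoid follicles between animals and an effect of the genotype cannot be told apart, since the exact permutation p of the list mean was 0.1, the smallest that 3 against 3 can give. The real split gave a difference of 1.91 and the highest of the other 9 splits 1.28.

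Control replicate 1 stood apart from the other libraries on the second principal component, which held 28.4% of the variance. Smooth muscle RNA added to it as the whole cause is argued against, since 97 genes outside that list were under 0.5 times the mean of the others and below each of them, where the other libraries had 0 to 27 such genes. For a swap with a knockout library, its B cell list mean lay 0.948 (log2) below the lowest knockout library, with an SD among controls of 0.226. B cell content does not give the genotype, so this cannot decide on a swap. Smad4, the targeted gene, was at 131.6 CPM in control replicate 1 and at most 102.1 CPM in a knockout library. That level goes against a swap, but the Smad4 difference between groups did not pass the threshold. A more distal stretch of colon may account for part of it, since posterior Hox genes (8 genes) minus anterior ones (17 genes) were 1.652 (log2) above the mean of the other 5 libraries, whose SD was 0.605. Knockout replicate 2 was next at 2.34, against 3.01 in control replicate 1, and individual variation between mice stays open.

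The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. With the quasi-likelihood test the real split called 0 genes and the highest other 0, so all 10 splits gave as many. With DESeq2 the real split called 336 and the highest other 97, and with the exact test 381 and 36, so 1 split of the 10 gave as many. With camera the real split called 16 lists and the highest other 17, so 2 of 10 gave as many. That other split set control replicates 1 and 2 and knockout replicate 3 against the rest.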
